A study of Mus musculus with 6 samples.

How the data were processed

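The deposited files cover 6 poly(A) RNA-seq libraries of mouse CD8 T cells, 3 cultured with supernatant of basophils kept with IL-3 and 3 with supernatant of basophils kept with PBS. Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, RSEM 1.2.12 with Bowtie2 2.2.0 was used against GRCm38, and edgeR 3.20.9 is named too. The role and order of these tools, the annotation and the setting for strand are not given in the sources used here. Per the labels' protocols, libraries were made with an Illumina TruSeq kit after poly(A) capture.

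Each library had a table of expected counts per gene, as deposited by the authors, with 46517 gene identifiers. Expected counts divide a read that fits several genes or isoforms among them, so they need not be whole, and between 5108 and 5896 genes per library held a fraction. They were rounded to whole numbers before testing. Each library also had a deposited table of TPM, the authors' transcript abundances scaled for length and library, per gene in 5 libraries and per isoform in PBS supernatant replicate 2. Gene symbols came from the reference's table of gene names, which matched 46005 identifiers. The other 512 kept their identifiers and held at most 0.202% of a library's counts. Coordinates are those of the GENCODE annotation of GRCm38.

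Totals of expected counts ranged from 17377052 to 22174902. The main test was edgeR 4.0.16 in R 4.3.3: filterByExpr on the groups, TMM factors, robust dispersions, a quasi-likelihood fit with 1 term for group and no block, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 12407 genes, which held at least 99.9% of the counts of every library. Log2 fold changes are IL-3 minus PBS supernatant, and each SE was derived from the F statistic of the fit. CPM use the TMM-scaled library sizes and are given as mean ± SD over 3 libraries. The common biological coefficient of variation was 0.0939. Gene lists fixed before the data were examined were tested with limma 3.58.1 on log2 CPM (prior count 2): camera with a preset correlation of 0.01, then camera with an estimated correlation, and fry, for lists with at least 4 tested members. Fry asks whether the genes of a list move on balance one way, not whether they differ from other genes. Principal components and correlations used the same log2 CPM. For genes with 1 to 3 counts over a group, the ratio of summed counts scaled by library size is given with an exact binomial interval at 95%. No pair of libraries in a group agreed within sampling noise, so all 6 counted as separate.

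Genes named in the text follow a rule fixed at the same time as the lists. They are the 10 highest and 10 lowest log2 fold changes among called genes with average log2 CPM of 2 or more, no overlap between groups and a symbol that is not a model name. To these are added up to 4 members of each list with the smallest p and a fixed panel of T cell genes given whatever the result. Genes named outside it are marked as chosen after their values were seen. Some results that would fall under the rule are not reported.

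The test was tried on simulated data: counts drawn for the 12407 genes from the means and library sizes of this comparison, with 50 genes changed at each of 4 fold sizes. It recovered 20% of genes changed 1.25-fold, 72% of those changed 1.5-fold, 72% of those changed 2-fold and 90% of those changed 4-fold. It made 11 false calls (7.97% of calls). A far smaller share of genes changed in the simulation than the 30.9% called in the data. The p-value that passes the adjustment depends on that share, so these rates need not hold for the data. Camera called 0 of 20 unchanged simulated lists. A simulated list of 20 genes changed 1.5-fold had camera adjusted p = 6.0e-30 with the preset correlation. With an estimated correlation it had camera adjusted p = 0.014. The simulated genes were drawn independently of each other, whereas the correlation estimated for the amino acid response and ATF4 list was 0.499. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists of correlated genes.

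Alternatives fixed in advance were DESeq2 size factors, library size only, no filter, a filter at CPM 1, the replicate number as a block, each library left out, DESeq2 1.42.0, limma-voom, limma on log2 TPM with pseudocounts of 1 and 0.1 and without a filter, a test against a fold of 1.2, an adjusted p below 0.01, and the other set tests. Added after seeing the data were fits without CT010467.1, with trends on GC content and length removed, and on TPM of 6 libraries, the isoform values of 1 library being summed per gene (99.7% of its TPM matched a gene). Tables were read with Python 3.11.15 and pandas 2.3.3 and plots drawn with matplotlib 3.10.9.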

Results

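The series asked how the transcriptome of mouse CD8 T cells changes when the cells are activated in the presence of supernatant from basophils. Basophils are rare granulocytes that respond to the cytokine IL-3. Naive T cells of C57BL/6J mice were stimulated for 3 days with plate-bound antibody to CD3, antibody to CD28 and IL-2. Between day 1 and day 2 they received supernatant of sorted basophils that had been kept for 2 days with IL-2 and either IL-3 at 3 ng/mL or PBS. Polyadenylated RNA was sequenced from 3 libraries per group, 6 in all. Summed expected counts came to 17893550, 18753617 and 17377052 for PBS supernatant replicates 1, 2 and 3, and to 19374216, 22174902 and 19283416 for IL-3 supernatant replicates 1, 2 and 3. A count of 0 in a library allows at most 0.135 to 0.173 CPM (counts scaled to library size), taking 3 counts as the limit, and this covers counting error only. The labels do not say whether replicates came from separate mice or cultures, so p-values measure the spread between these libraries, which may be technical.

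With IL-3 basophil supernatant, CD8 T cells carried far more transcript of type 2 cytokines and of the colony-stimulating factors Il3 and Csf2, more Gzmb and Ifng transcript, and less of most interferon-response genes, of 5 of 8 NK-type receptors and of Cd8a than with PBS basophil supernatant. As sets, the type 2, interferon and NK-type receptor lists passed camera with a preset correlation but not with an estimated correlation (adjusted p = 0.126 for the first and adjusted p = 0.280 for the others). Of 12407 genes tested, 1834 were higher and 2001 lower with IL-3 supernatant at an adjusted p below 0.05 in edgeR's quasi-likelihood test (Benjamini-Hochberg). The change was at least 2-fold for 539 of the higher and 427 of the lower genes, and the median changed gene differed 1.41-fold. In 5409 genes (43.6%) the 3 values of one group did not overlap the 3 of the other, where chance gives 10%. The first principal component held 63.0% of the variance and separated the groups, and the second held 14.7% and set PBS supernatant replicate 2 apart. Pearson correlations of log2 CPM across genes were 0.981 to 0.989 within groups and 0.954 to 0.961 between groups. CT010467.1, a single gene of the annotation, took 4.51% of the counts of PBS supernatant replicate 2 and 0.612% and 0.433% of those of replicates 1 and 3, and it took between 0.437% and 2.2% of those of the IL-3 supernatant libraries.

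Among called genes with an average log2 CPM of at least 2 and no overlap between groups, the 3 highest fold increases were in cytokine genes. Il13 (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702, GRCm38), a type 2 cytokine, stood at 0.245 ± 0.232 CPM with PBS supernatant and 249 ± 26.6 CPM with IL-3 supernatant (SD, n = 3 each). Its log2 fold change was 9.97 (SE 0.23, edgeR adjusted p = 3.9e-09), and 11.05 without PBS supernatant replicate 3, which held 9 of the 13 counts of that group. Il24 (ENSMUSG00000026420, chromosome 1, 130882074 to 130887454), a cytokine of the IL-10 family, went from 0.409 ± 0.230 to 171 ± 19.1 CPM, a log2 fold change of 8.68 (SE 0.18). Inhba (ENSMUSG00000041324, chromosome 13, 16011851 to 16031621), which encodes a subunit of activin, went from 0.298 ± 0.0607 to 57.5 ± 1.75 CPM, a log2 fold change of 7.56 (SE 0.15). The other genes that led the increases were Akr1c18, a hydroxysteroid dehydrogenase, at log2 6.71, the kinase gene Lrrk2 at 5.68, Il10 at 5.39, the scaffold gene Ajuba at 5.06, the chemokine receptor gene Ccr8 at 4.95, the dicarboxylate transporter gene Slc13a3 at 4.82 and Il3 at 4.68. For Il10 the value was 7.76 without PBS supernatant replicate 2, whose 0.831 CPM was the highest of its group.

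By the same criteria, the 10 deepest falls included 3 members of the interferon-inducible Ifi200 family. Ifi206 (ENSMUSG00000037849, chromosome 1, 173468485 to 173491041) went from 8.63 ± 1.06 to 0.113 ± 0.0188 CPM (SD, n = 3 each), a log2 fold change of -6.16 (SE 0.32). Ifi203 (ENSMUSG00000039997, chromosome 1, 173920407 to 173942672) went from 49.9 ± 5.27 to 1.82 ± 0.651 CPM, a log2 fold change of -4.75 (SE 0.18). Ifi209 had a log2 fold change of -3.93. Genes of this family resemble each other in sequence, so how reads were divided among them is uncertain. St6gal1 (ENSMUSG00000022885, chromosome 16, 23224740 to 23360350), a sialyltransferase, went from 38.3 ± 0.657 to 1.78 ± 0.674 CPM, at log2 -4.44 (SE 0.17). The axonemal gene Drc1 (-4.32), the trafficking regulator Klf2 (-3.91), Fgl2 (-3.81), Itih5 (-3.73), Igfbp7 (-3.62) and Ms4a4b (-3.52) completed the 10.

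**Figure D1:**
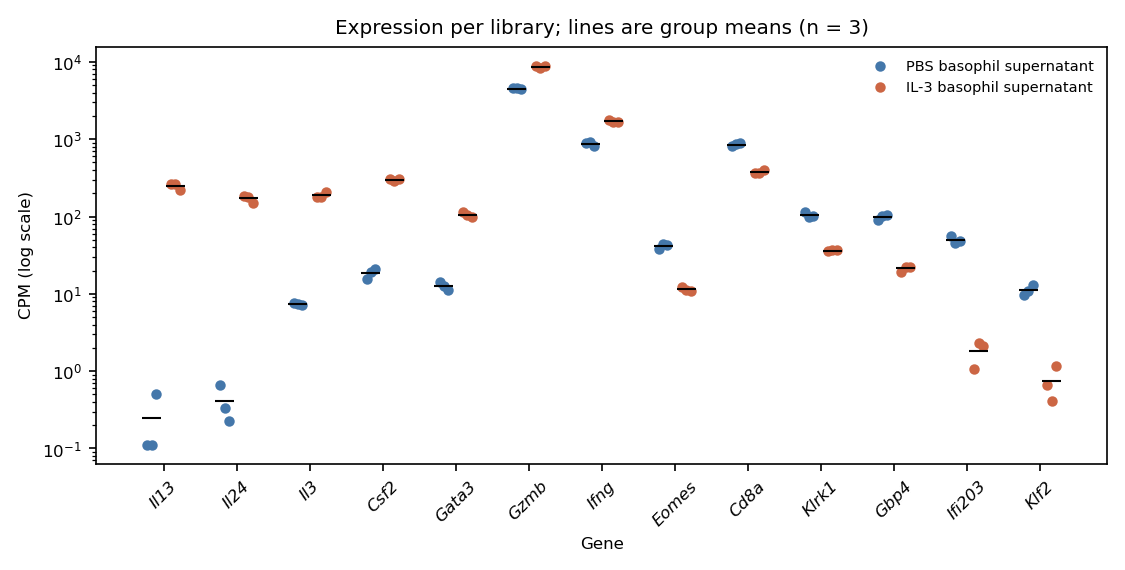
CPM per library on a log axis for 13 genes, with points for the 3 libraries of each group and a line at each group mean. Il13 rose from 0.245 to 249 CPM and Gzmb from 4525 to 8688 CPM, and Cd8a fell from 850 to 377 CPM.

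Among 13 tested type 2 cytokines and their regulators, 8 rose, 2 fell and 3 did not pass (8 rose and 3 fell adjusted over the list alone). Csf2, which encodes GM-CSF, went from 18.6 ± 2.73 to 301 ± 8.63 CPM (SD, n = 3 each), at log2 4.01 (SE 0.09, edgeR adjusted p = 1.7e-13). Gata3, the lineage factor of type 2 T cells, went from 12.7 ± 1.51 to 106 ± 7.51 CPM, at log2 3.06. Il4 had 0, 0 and 1 counts in the PBS supernatant libraries and 70, 103 and 69 in the IL-3 supernatant libraries, a ratio of 212 (95% exact counting interval 37.6 to 8397) whose lower group rests on 1 count of replicate 3. Il9 had 1 count over the PBS supernatant group and 192 over the IL-3 supernatant group, a ratio of 168 (29.8 to 6669). Il5 was below the filter, with 4 counts over the PBS supernatant group and 18 over the IL-3 supernatant group. The list was higher as a set (camera, adjusted p = 0.00030), with adjusted p = 0.126 with an estimated correlation. Of 18 tested IL-4 and STAT6 targets, 14 rose and 3 fell (14 and 3 adjusted over the list alone), among them Ccr8, Il24 and Epas1, the last at log2 4.52 (SE 0.20). Ccr4, another chemokine receptor of type 2 cells, rose by log2 1.37, and the IL-4 receptor gene Il4ra (0.56), Socs1 (0.82) and Cish (0.44) rose less. The set was higher by camera (adjusted p = 1.0e-06), with adjusted p = 0.126 with an estimated correlation.

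**Figure D2:**
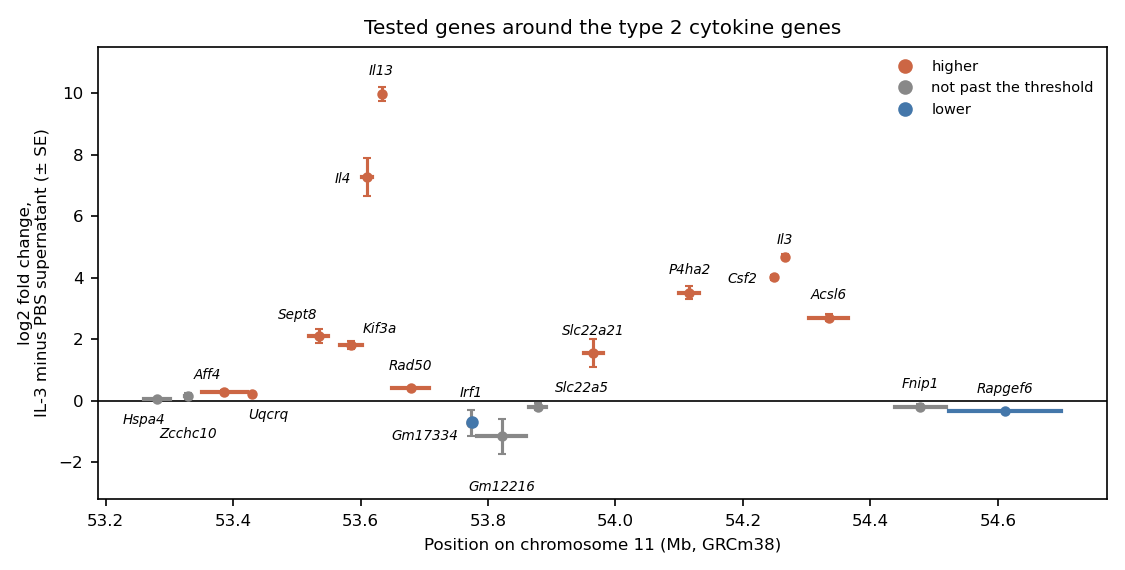
Log2 fold change (IL-3 minus PBS supernatant, with SE) of tested genes by position on chromosome 11 (Mb, GRCm38) around the cytokine genes Il4, Il13, Csf2 and Il3. Il13 stood at 9.97, Il3 at 4.68 and Csf2 at 4.01, with Acsl6 at 2.70 and Rapgef6 at -0.35 among their neighbours, and the fitted value of Il4 rests on 1 count with PBS supernatant.

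Of 15 tested cytotoxic effector molecules, 9 rose, 3 fell and 3 did not pass (10 rose and 3 fell adjusted over the list alone). Gzmb, which encodes granzyme B, was already abundant at 4525 ± 110 CPM and reached 8688 ± 226 CPM (SD, n = 3 each), a log2 fold change of 0.94 (SE 0.05, edgeR adjusted p = 2.3e-10). Gzmc rose by log2 2.34 and Gzma by 4.17, the latter from 0.390 to 7.18 CPM. The granzymes are a gene family with similar sequences, so the split of reads among the rarer ones is uncertain. Serpinb9, an inhibitor of granzyme B, rose by log2 1.95 and the related Serpinb6b by 2.09. Prf1, which encodes perforin, was at 109 ± 8.09 and 119 ± 5.80 CPM and did not pass (adjusted p = 0.20), and Gzmk had 1 count over the PBS supernatant group and 0 over the other. The set was higher (camera, adjusted p = 0.0020), with adjusted p = 0.321 with an estimated correlation. T cell cytokines and chemokines went both ways, with 9 of 19 higher and 6 lower (the same counts adjusted over the list alone). Ifng rose from 876 ± 57.3 to 1701 ± 41.6 CPM (log2 0.96, SE 0.05), whereas Ltb (log2 -2.89), Ccl1 (-2.25), Il16 (-1.32), Ccl3 (-0.49) and Ccl4 (-0.25) fell, and Ccl5 did not pass (adjusted p = 0.43). This list's median log2 fold change was -0.01 and its mean 0.61; camera leaned up and fry down, and neither passed.

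Transcription factors of effector cells moved apart. Eomes, a T-box factor of memory and cytotoxic cells, fell by 1.86 on the log2 scale from 41.6 ± 3.35 CPM (SD, n = 3; SE 0.10, edgeR adjusted p = 3.1e-10), while Tbx21, which encodes T-bet, rose by log2 0.41. Batf (1.08), Batf3 (0.96) and Bhlhe40 (0.77) rose, and of 14 tested factors 7 rose and 2 fell (7 and 3 adjusted over the list alone). Of 19 naive and memory genes 4 rose and 11 fell (5 and 11 adjusted over the list alone). Klf2, Ly6c2 (log2 -2.52), Il6ra (-2.12), Myb (-1.26) and Tcf7 (-0.56) fell, the chromatin organizer Satb1 rose by 1.67, and Il7r did not pass (0.22, SE 0.10). The set was lower (camera, adjusted p = 0.028), with adjusted p = 0.280 with an estimated correlation, and it lost the call without PBS supernatant replicate 1 (adjusted p = 0.076). Il7r passed without that replicate (log2 0.36), with no filter (adjusted p = 0.017) and with GC and length trends removed (adjusted p = 0.027). Of 18 inhibitory receptors and exhaustion-associated genes 4 rose and 7 fell (5 and 8 adjusted over the list alone), and the set did not pass (camera, adjusted p = 0.057), though it did under several other settings (adjusted p from 0.013 to 0.503 over the alternatives of camera). Tox, a regulator of exhaustion, fell by 1.59 on the log2 scale, Cd101 by 2.77 and Vsir by 0.99, Cd200 rose by 0.79, and Pdcd1 (-0.07, SE 0.07) and Havcr2 (-0.20, SE 0.18) did not pass. Of 19 activation and costimulation genes 10 rose and 5 fell (10 and 6 adjusted over the list alone). The costimulatory receptors Tnfrsf4 (log2 1.47) and Tnfrsf18 (0.80), Cd44 (0.43) and the IL-2 receptor gene Il2ra (0.34) rose, and Icos (-1.05) and Cd69 (-0.68) fell.

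Many targets of several signalling pathways rose. Some lists share members, such as Il4ra, Socs1 and Cish between IL-4 and IL-2 targets, so their counts are not independent. Of 24 amino acid response and ATF4 targets 21 rose and none fell (the same counts adjusted over the list alone). They include the arginine transporter gene Slc7a3 (log2 2.01, SE 0.11), Asns, which encodes asparagine synthetase (1.31), Sesn2 (1.02) and the serine synthesis gene Psph (0.83). The set gave camera adjusted p = 2.1e-09, and adjusted p = 0.321 with an estimated correlation. Of 20 IL-2 and STAT5 targets 13 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.00029, and adjusted p = 0.126 with an estimated correlation), among them Cdkn1a (log2 1.27, SE 0.05) and Lif (1.45), which encodes a cytokine of the IL-6 family. Of 17 IL-6 and STAT3 targets 13 rose and 2 fell (14 and 2 adjusted over the list alone; camera adjusted p = 2.3e-05, and adjusted p = 0.126 with an estimated correlation). Batf, Junb (0.74) and Socs3 (0.97) rose and Fgl2 fell. Il21 had 2 counts over the PBS supernatant group, both in replicate 1, and 426 over the IL-3 supernatant group, a ratio of 186 (95% exact counting interval 51.3 to 1544). Of 20 NF-kB targets 12 rose and 1, Irf1, fell (13 and 1 adjusted over the list alone; camera adjusted p = 0.00029, and adjusted p = 0.189 with an estimated correlation). Ier3 (2.14), Traf1 (1.01), Map3k8 (0.94) and Nfkb2 (0.60) were among those that rose.

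Many interferon-response genes fell. Of 24 interferon-gamma and antigen presentation genes 20 fell and 2 rose (21 and 3 adjusted over the list alone). The guanylate-binding protein genes Gbp6, Gbp7 and Gbp4, interferon-induced GTPases, fell, Gbp6 by 2.54 on the log2 scale (SE 0.09), Gbp4 from 98.4 ± 7.73 to 21.3 ± 2.06 CPM (SD, n = 3 each; edgeR adjusted p = 6.1e-12), and Serpina3g by 2.45. The risers were Cd274, which encodes PD-L1, and Socs1, a feedback inhibitor of cytokine signalling. Of 18 type I interferon response genes 10 fell and 1, Oasl1, rose (10 and 1 adjusted over the list alone). Zbp1, a sensor of nucleic acids, fell by 1.02 on the log2 scale (SE 0.14), and Ifit2 (-0.94) and Isg20 were lower too. Both sets were lower by camera, at adjusted p = 9.4e-09 for the first and adjusted p = 0.0014 for the second, with adjusted p = 0.280 with an estimated correlation for each. Ifng transcript itself was higher in the same libraries.

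Receptors for migration and NK-type receptors were mostly lower. Of 19 chemokine and homing receptors 12 fell and 5 rose (12 and 5 adjusted over the list alone; camera adjusted p = 0.061, and from 0.018 to 0.280 over the alternatives of camera). Cxcr3 (log2 -1.90, SE 0.13), a receptor of type 1 effector cells, fell, opposite to Ccr8 and Ccr4. Of 8 NK-type receptors 5 fell and none rose (5 and 0 adjusted over the list alone). Klrk1, which encodes NKG2D, fell from 105 ± 7.27 to 36.1 ± 0.670 CPM (SD, n = 3 each; log2 -1.53, edgeR adjusted p = 3.2e-11), and Klrd1 (-1.17), Klrc1 (-0.77) and Cd160 (-0.74) fell with it. The set was lower (camera, adjusted p = 0.010), with adjusted p = 0.280 with an estimated correlation.

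Most cell cycle genes were slightly lower, and most DNA replication genes did not pass. Of 20 cell cycle genes 12 fell and none rose (14 fell and 1 rose adjusted over the list alone), by small amounts such as 0.35 on the log2 scale for Mki67 (1328 ± 23.3 to 1040 ± 28.5 CPM, SD, n = 3 each), 0.50 for Ccnb2, 0.44 for Cenpa and 0.31 for Kif11. Of 24 DNA replication genes 8 fell and none rose (12 and 0 adjusted over the list alone), for example Mcm6 (-0.27) and Mcm7 (-0.25). Camera gave adjusted p = 6.5e-04 for the first set and adjusted p = 0.0089 for the second, and these became adjusted p = 0.310 and adjusted p = 0.618 with an estimated correlation. Metabolic lists held genes that rose and genes that fell. Of 20 glycolysis genes 3 rose and 3 fell (5 and 4 adjusted over the list alone), with the hexokinase gene Hk2 higher (log2 0.82) and Pdk1 lower (-0.63). Of 18 hypoxia-responsive genes 5 rose and 4 fell (7 and 6 adjusted over the list alone), with Egln3 at log2 1.83 and the prolyl hydroxylase gene P4ha2 at 3.51. Of 27 oxidative phosphorylation genes 1, Cycs, rose (log2 0.27) and 1, Sdhb, fell (1 and 0 adjusted over the list alone), of 23 cholesterol synthesis genes 2 rose and 6 fell (2 and 6), and of 21 fatty acid synthesis and oxidation genes 7 rose and 3 fell (7 and 5), with Cpt1a, of fatty acid import into mitochondria, lower (-0.71). Of 20 unfolded protein response genes 6 rose and 4 fell (8 and 4), of 15 heat shock proteins 8 rose and 1 fell (8 and 2), with Hspa1a higher (1.85), and of 22 p53 targets and apoptosis genes 9 rose and 5 fell (11 and 5). Bcl2l11, which encodes the pro-apoptotic protein BIM, fell by 1.97 on the log2 scale. Of 20 immediate early and dissociation genes 8 rose and 3 fell (9 and 4), with Atf3 higher (1.93) and Egr3 lower (-1.53). Of 17 TGF-beta targets and residency genes 5 rose and 4 fell (6 and 4), with Rgs2 (1.56) higher. Of 20 ribosome biogenesis genes 3 rose and 1 fell (3 and 1), and of 28 ribosomal protein genes 2, Rpl27 and Rplp0, rose (0 adjusted over the list alone). The gene Sdhb lost its call without replicates 2 or 3 of either group (adjusted p from 0.127 to 0.245), with the replicate block (0.0908), by DESeq2 (0.0814), with DESeq2 size factors (0.0601), by library size only (0.0833), on TPM and without CT010467.1 (0.0598). The call of the gene Rplp0 was lost with the replicate block (adjusted p = 0.082), on TPM of 5 libraries and without replicates 1 or 3 of either group (adjusted p from 0.0527 to 0.134). The gene Rpl27 lost it without any library but PBS supernatant replicate 2 (adjusted p from 0.0551 to 0.147). No member of the 13 mitochondrially encoded genes or of the 18 replication-dependent histones passed, by edgeR or adjusted over the list alone. None of these lists from glycolysis on passed camera, nor did those of effector factors and activation.

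**Figure D3:**
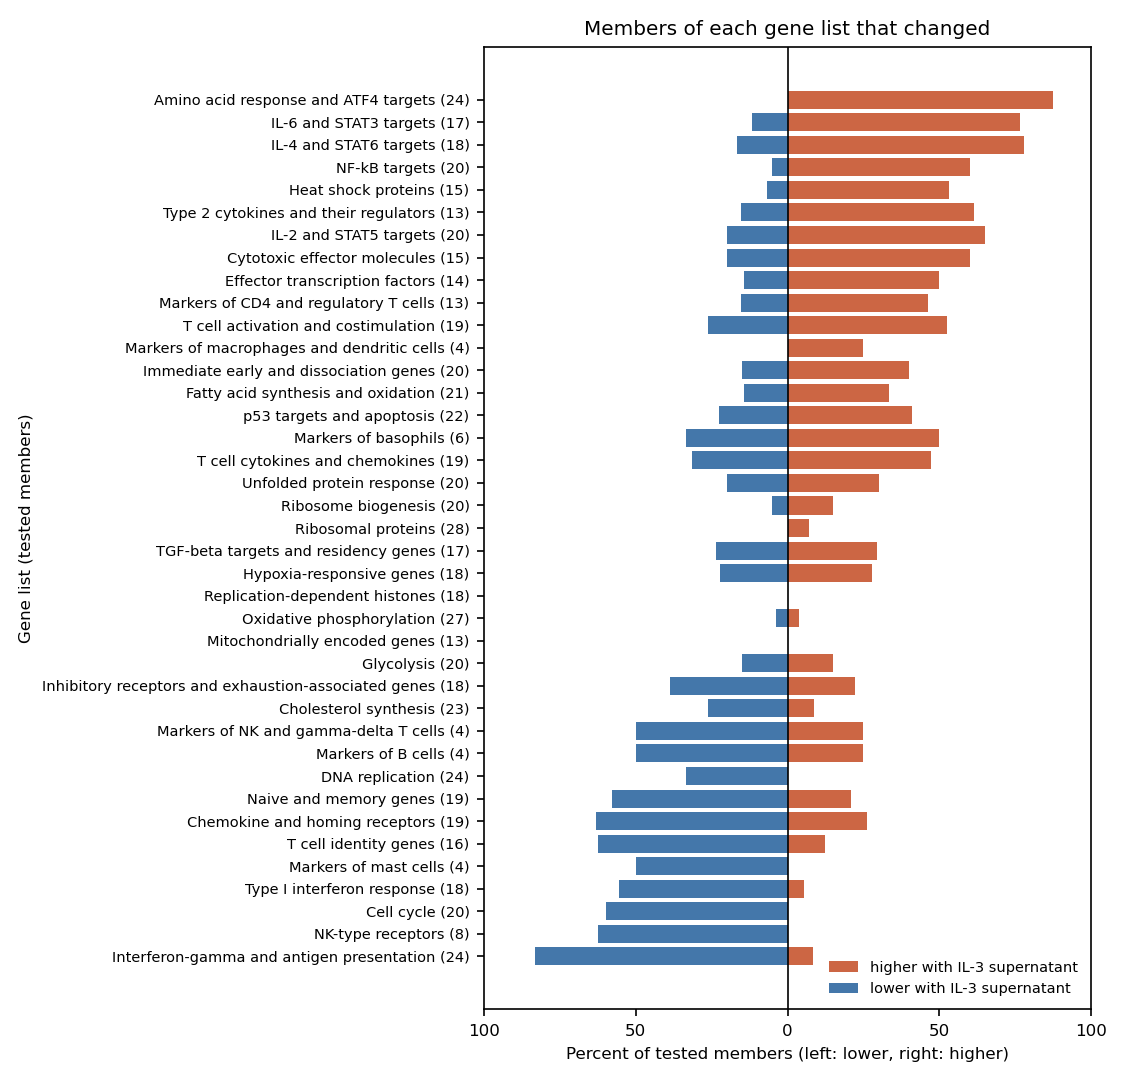
Share of tested members of each gene list called higher (right) or lower (left) with IL-3 supernatant, in percent, with the number of tested members in brackets. Of the amino acid response and ATF4 targets 87.5% were higher, and of the interferon-gamma and antigen presentation genes 83.3% were lower.

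Some members went against the rest of their list, and those in this paragraph, like Il9, Irf1, Cd274, Oasl1, Acsl6 and Rapgef6, were named after their values were seen. Among type 2 genes the receptor genes Il1rl1 (log2 -1.21) and Crlf2 (-0.46) fell, and among IL-4 and STAT6 targets Il1rl1, Xbp1 (-0.34) and Igfbp7. Among cytotoxic molecules the cathepsin genes Ctsw (-0.78), Ctsd (-0.31) and Ctsc (-0.17) fell, and among effector factors Prdm1, which encodes Blimp-1, fell (-1.12) with Eomes. Among IL-2 and STAT5 targets Socs2 (-1.38), Pim2 (-0.50), the survival gene Bcl2 (-0.48) and the cyclin gene Ccnd3 (-0.35) fell, and among IL-6 and STAT3 targets the receptor gene Il6st (-0.67). Among naive and memory genes Lef1 (0.23), S1pr1 (0.64) and Dapl1 (0.66) rose with Satb1, and among inhibitory receptors Lag3 (0.74), Btla (0.27) and Nr4a2 (0.32) rose with Cd200. Among activation genes Il2rg (-0.24), Cd28 (-0.52) and Myc (-0.22) fell with Icos and Cd69. The receptors that rose were Ccr8, Ccr4, S1pr1, Cxcr5 (1.38) and Itgb1 (0.33), and the NK-type receptor Klrc2 (-1.21) fell. The calls of some of these genes were lost without 1 library. Cxcr5 lost its call without IL-3 supernatant replicate 1 (adjusted p = 0.0503), and Myc without PBS supernatant replicate 2 (0.0518) or IL-3 supernatant replicate 2 (0.0656). S1pr1 lost it without PBS supernatant replicates 2 (0.0802) or 3 (0.073) or IL-3 supernatant replicate 1 (0.0923). Lef1 lost it without PBS supernatant replicates 2 (0.0627) or 3 (0.0954) or IL-3 supernatant replicates 1 (0.0918) or 3 (0.133). Ctsc and Btla lost it without replicates 2 or 3 of either group, with adjusted p from 0.0656 to 0.105 for Ctsc and from 0.0699 to 0.107 for Btla, and with the replicate block (0.0561 and 0.0552). The gene Ctsc lost it by library size only too (0.0764), and the gene S1pr1 by DESeq2 (0.0527). On log2 TPM the calls of Lef1, S1pr1, Myc and Btla were lost with 5 and with 6 libraries. With 5 libraries the gene Prdm1 (adjusted p = 0.072 and 0.0846 by pseudocount), Cxcr5 and Oasl1 lost theirs too. With 6 libraries Ctsc did, and so did the gene Pim2, at log2 -0.22 (adjusted p = 0.626). With 5 libraries and no filter, those of Bcl2, Cd28, Ctsd, Dapl1, Il1rl1, Il2rg, Irf1, Itgb1, Klrc2, Nr4a2 and Xbp1 were lost as well.

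Most genes of T cell identity were lower. Cd8a, the alpha chain of the CD8 co-receptor, fell from 850 ± 41.1 to 377 ± 15.5 CPM (SD, n = 3 each; log2 -1.17, SE 0.05, edgeR adjusted p = 5.7e-11), and Cd8b1, its beta chain, by 0.42 on the log2 scale. The T cell receptor complex genes Cd3e (-0.75) and Cd3g (-0.57) and the surface marker gene Thy1 (-0.45) fell, and 10 of the 16 identity genes fell in all (11 adjusted over the list alone). The 2 that rose, Cd5 and Cd247, are named after their values were seen. The set was lower (camera, adjusted p = 0.0020), with adjusted p = 0.545 with an estimated correlation.

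Among markers of other cells, most of those of CD4 and regulatory T cells and few of those of the remaining types could be tested. Of 19 basophil markers, 4 of them shared with other lists, 6 could be tested. Of these 3 rose (Il4, Cyp11a1 and Csf1) and 2, Ifitm1 and Ccl3, fell. Il4 is also in the type 2 list, and Csf1 and Ccl3 in that of T cell cytokines and chemokines. The gene Cyp11a1, which encodes a steroid synthesis enzyme, had a log2 fold change of 4.54 (SE 0.53), or 5.47 without PBS supernatant replicate 2. The basophil protease genes Mcpt8 and Prss34 and the IgE receptor genes Fcer1a and Ms4a2 had 0 counts in every library. Of 13 tested markers of CD4 and regulatory T cells, 7 of them shared with other lists, 6 rose and 2 fell (6 and 3 adjusted over the list alone). Foxp3, the lineage factor of regulatory T cells, went from 7.34 ± 2.38 to 0.163 ± 0.104 CPM (SD, n = 3 each; log2 -5.43, SE 0.42), Lrrc32 fell by 1.51 on the log2 scale, and Zbtb7b, the factor of CD4 lineage choice, was higher. Cd4 itself stayed below the filter with 37 counts over the PBS supernatant group and 19 over the other. Of 4 tested B cell markers Ebf1 rose (log2 3.51), and Ighm (307 ± 16.2 to 117 ± 10.8 CPM, SD, n = 3 each) and the gene Ighd (log2 -2.39, or -3.02 without IL-3 supernatant replicate 3) fell. Cd79a, another B cell marker, had 10 counts over the PBS supernatant group and 11 over the IL-3 supernatant group. The B cell marker Ms4a1 had 8 and 6. Of 4 tested mast cell markers Kit (-2.15) and Gata1 (-1.78) fell, each from under 3 CPM, and Gata1 lost its call without IL-3 supernatant replicate 1 (adjusted p = 0.064), without IL-3 supernatant replicate 2 (adjusted p = 0.052) or without PBS supernatant replicate 2 (adjusted p = 0.12). Of 4 markers of macrophages and dendritic cells 1, H2-Ab1, rose (log2 1.33), and of 4 of NK and gamma-delta T cells, Gzma rose and Eomes and Tcrg-C2 (-1.88) fell. The single tested neutrophil and eosinophil marker did not pass, and the single tested marker of erythroid cells, platelets and stroma, Pecam1, fell by 2.38. Ifitm1 lost its call without PBS supernatant replicates 1 (adjusted p = 0.0503) or 3 (0.13) or IL-3 supernatant replicates 1 (0.0911) or 3 (0.0688), and by DESeq2 (0.0513). Ifitm1, Cd4, Cd79a, Ms4a1, Mcpt8, Prss34, Fcer1a and Ms4a2 were named after their values were seen. None of the marker lists with at least 4 tested members passed camera. Median and mean log2 fold change had opposite signs in the lists of hypoxia-responsive genes, cholesterol synthesis, CD4 and regulatory T cells, macrophages and dendritic cells, and NK and gamma-delta T cells.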

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

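Fits without CT010467.1, with GC and length trends removed and on TPM of 6 libraries were chosen after seeing the data. No called gene was called in the opposite direction under any of these settings. Counts of higher and lower genes stayed within 1.5 times under other scalings, filters, DESeq2 and limma-voom, and without 1 library at a time, where they ranged from 1456 to 1916 higher and from 1601 to 2102 lower. They fell to 928 and 937 against a fold of 1.2 and to 1217 higher at an adjusted p below 0.01, both stricter by construction. On log2 TPM of 5 libraries they fell to 1134 and 1144 higher with pseudocounts of 1 and 0.1. With no filter there, 669 were higher and 820 lower. The main test on those 5 libraries, without PBS supernatant replicate 2, gave 1681 higher and 1652 lower. On TPM of 6 libraries 1430 were higher and 1378 lower. Fewer libraries alone therefore do not account for the lower counts on TPM, and the cause was not tested. Without CT010467.1 the counts were 1877 and 1938. Deviations from group means did not show a pairing by replicate number. Same-numbered deviations correlated at -0.148, 0.052 and 0.255, and other pairs at -0.284 to 0.256. These few values depend on each other and cannot exclude a shared mouse, culture or day, which the labels do not give. With the replicate block 1634 genes were higher and 1776 lower. Camera called 7 lists higher and 7 lower. With an estimated correlation it called 0 and 0, where at unadjusted p below 0.05 5 higher and 1 lower would pass, and fry called 13 and 13. The estimate was below the preset 0.01 for type 2 cytokines (-0.046) and for IL-4 (0.0054), IL-2 (-0.019) and IL-6 (-0.0019) targets. A higher correlation thus does not explain the larger p-values of those lists. In the other lists called with the preset correlation the estimate was above 0.01. Without 1 library, 7 lists stayed higher and 7 to 9 were lower. The chemokine receptor list passed without IL-3 supernatant replicate 3 (adjusted p = 0.018), by library size only (0.037), at CPM 1 (0.038), with no filter (0.018), with GC and length trends removed (0.042) and by fry (0.00017), and the inhibitory receptor list without PBS supernatant replicate 3 (adjusted p = 0.033), IL-3 supernatant replicate 2 (0.048) or IL-3 supernatant replicate 3 (0.027), with the replicate block (0.048), by library size only (0.042), with no filter (0.013) and by fry (0.0015). The histone list passed without PBS supernatant replicate 1 (0.044) and turned its direction without PBS supernatant replicate 2 (adjusted p = 0.844), and the mitochondrial list passed without IL-3 supernatant replicate 2 (0.027); the cause was not tested. Of 172 named genes, none reversed under 20 settings; over genes and settings, 160 calls were lost and 3 gained, with 47 lost on TPM of 5 libraries with no filter, 29 against a fold of 1.2, 12 on TPM of 5 libraries at either pseudocount (among them Ccl4, Aff4 and Uqcrq) and 7 on TPM of 6 libraries. Depth limits genes with few counts, such as Il4, Il5 and Il21.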

Other observations

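The families in this paragraph were picked after the values were seen, so their counts are given without a test. All 10 tested guanylate-binding protein genes fell, from -1.09 to -3.16 on the log2 scale, though reads shared among such similar genes are uncertain in their split. Of 9 tested genes of the Ifi200 family 8 fell, and Aim2, a DNA sensor, rose by log2 0.34. Serpins went mostly the other way, with 7 of 12 higher and 2 lower. Of 9 genes with Gimap names 5 fell and none rose, and Gimap1os, annotated as a processed transcript, did not pass. The 2 chains of the IL-18 receptor fell together, Il18r1 from 105 ± 3.39 to 20.9 ± 2.43 CPM and Il18rap from 68.4 ± 3.70 to 12.9 ± 0.265 CPM (SD, n = 3 each), while both chains of the IL-12 receptor rose, Il12rb2 by log2 1.23 and Il12rb1 by log2 0.79. Of 71 tested T cell receptor variable segments 18 fell and none rose, and their reads are hard to assign. Another group of 12 genes was picked by name alone: Akr1c18, Cyp11a1 and names starting with Hsd, which need not all act on steroids. In it Akr1c18, Cyp11a1 and Hsd17b4 rose, while Hsd11b1 (by 3.21 on the log2 scale), Hsdl1 and Hsdl2 fell. Of 7 genes with Schlafen names 3 fell and 1, the pseudogene Slfn10-ps, rose. Under other scalings these counts were the same, except that 17 variable segments and 2 genes of the group with Akr1c18 and Cyp11a1 fell by library size only.

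The tests on carried-over, CD4 and receptor transcripts and on the spread of identity genes were chosen only after the results were seen. Type 2 cytokine transcripts were higher with IL-3 supernatant. RNA carried over from basophils would bring basophil transcripts with it, but the summed counts of Mcpt8, Prss34, Fcer1a, Ms4a2, Cpa3 and Cd200r3 were 0.0065% of those of Il13 in the IL-3 supernatant libraries, 1 count against 15284. A larger share of CD4 T cells would raise Cd4, but Cd4 counts were 0.124% of those of Il13 and not above those with PBS supernatant. This argues against a larger share of CD4 T cells, on a single gene with few counts. It does not exclude a strong response of a few CD4 T cells, which need not raise Cd4. IL-3 left in the supernatant may have acted on the T cells: the beta-chain genes Csf2rb and Csf2rb2 had 25 counts over 6 libraries, near the floor, while the alpha-chain gene Il3ra had 226 and 292 counts over the PBS and IL-3 supernatant groups, which leaves receptor protein open, and the series as analysed here has no library with IL-3 but no basophils, so IL-3 and basophil products cannot be told apart. A response of the T cells to basophil products stays open as well.

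Many interferon-response genes were lower with IL-3 supernatant. Of the 30 members of both interferon lists called lower, 30 stayed lower under both other scalings. With GC and length trends removed, 30 stayed lower too. The median log2 fold change of tested genes was -0.0047 in the main test, 0.0023 with DESeq2 size factors and 0.0163 by library size only. Such shifts could hardly undo falls with list medians of -0.66 (interferon-gamma) and -0.82 (type I), so the scaling check decides little. Log2 fold changes hardly followed GC content or length across genes (Spearman rho -0.0197 and 0.025), so that check was weak too. A change in the share of other cells was not weighed here and stays open, beside a weaker response of the T cells to interferon.

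Most T cell identity genes were lower with IL-3 supernatant. A lower share of T cells as the only cause would lower them alike, but their log2 fold changes spread 6.66 times as widely as their median standard error. CD4 T cells in place of CD8 T cells would raise Cd4, which stood at 0.064% of the fall of Cd8a in CPM. All 10 genes called lower stayed lower under both other scalings. Those scalings shift fold changes little, so this check decides little. A change within the T cells is a hypothesis that was not tested here.

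A further hypothesis was that the cytokine genes on chromosome 11 rose with their whole neighbourhood. Il4, Il13, Il5, Csf2 and Il3 lie between 53602982 and 54267277 (GRCm38). Among 15 other tested genes within 500 kb, leaving out P4ha2 because its rise (log2 3.51) had been seen before the bounds were set, 7 were higher, 2 were lower and 6 did not pass. The bounds set beforehand were at least 50% of neighbours for the hypothesis and no more than 20% against it, so the outcome decides neither. Counting P4ha2, 8 of 16 would be higher, which meets the first bound, so the outcome turns on that gene. Of all tested genes 14.8% were higher (Fisher's exact test without P4ha2, two-sided p = 0.0033). That test was not part of the bounds set beforehand. It takes genes as independent, which neighbours at the same locus need not be, so it does not decide the matter. The higher neighbours were Acsl6 (log2 2.70), Sept8 (2.10), Kif3a (1.81), Slc22a21 (1.54), Rad50 (0.40), Aff4 (0.29) and Uqcrq (0.23), and Irf1 (-0.70) and Rapgef6 (-0.35) were lower. Slc22a21 lost its call without IL-3 supernatant replicate 1 (adjusted p = 0.056), IL-3 supernatant replicate 2 (adjusted p = 0.069) or PBS supernatant replicate 3 (adjusted p = 0.073), and Uqcrq without IL-3 supernatant replicate 1 (adjusted p = 0.052). These neighbours were named after their values were seen.

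The 6 libraries can be split into 3 and 3 in 10 ways. The real split gave 3835 changed genes and the highest of the others gave 1. So 1 of the 10 splits, the real one itself, reached the real count. Every other split mixes the groups, which turns the group difference into spread within each side. Low counts there were bound to follow and do not measure the spread between libraries. With 10 splits the share cannot fall under 0.1.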
